A study of Drosophila melanogaster with 6 samples.

How the data were processed

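Poly(A) RNA-seq libraries of whole late-blastoderm embryos were compared, 3 from embryos injected with water and 3 from embryos injected with dsRNA against eve and run at 1 µg/µl each, per the labels' protocols. Eggs were collected over 0 to 1 h at 25 °C and injected, and the embryos were then kept at 18 °C until picked by their stage, about 50 per replicate. Nothing in the labels says whether replicates were injected on separate days, so p-values measure the spread between these collections. Groups and replicate numbers were taken from the sample titles, and there were 0 columns of other samples.

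The submitters' processing notes name TopHat2 version 2.0.9, Bowtie2, HTSeq and DESeq and the genome build dm3, without order or settings; the annotation release and the use of strand in counting are not given in the sources used here. The deposited values are a normalised signal per gene: in each library every value minus 1 was a whole multiple of one step (100% of values within 0.01 read). Each is therefore a read count divided by a factor of its library, with 1 added by the authors. The factors equalled median-of-ratios size factors computed from the whole reads with a ratio of 0.99996 to 1. Counts of reads per gene were obtained by dividing out the step. All 9073 listed genes had reads in at least 4 libraries, and genes without reads in a library numbered 7 to 171 of them, so every gene tested had been detected in most libraries; genes outside the list are not analysed here. Gene reads were 23234425 to 49364110 per library. Of all listed reads, rows that name no gene held 12.4% to 14.8% with a non-unique alignment, 0.72% to 0.75% ambiguous between genes and 4.32% to 4.91% outside genes; these 3 rows stayed out of every test. Reads that align to several places were not counted to genes, which lowers near-identical copies such as the Hsp70 genes, whose values are uncertain.

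Gene identifiers were CG numbers. Symbols and chromosome arms came from a RefSeq gene table of assembly Release 6 plus ISO1 MT, used for names only: 8982 of 9073 matched (8659 by locus tag, 299 by an older tag and 24 by synonym), and 91 kept their CG number. Where 1 symbol had several CG numbers (90 symbols), lists took the one with the higher mean. Lists defined by the start of a symbol, such as the ribosomal and histone lists, took all of them. Gene positions are those of the BDGP6 annotation, whose build differs from the dm3 of the authors, and no coordinate was converted. Among the 25 genes named in full, 4 have an exon overlapped by an exon of another gene, always on the other strand.

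Normalised counts (the deposited values minus 1) were tested as log2(normalised count + 1), which is the log2 of the deposited value, with limma 3.58.1 in R 4.3.3 (limma-trend, robust). The minimum mean of 1 fixed in advance removed 0 genes. P-values were adjusted by Benjamini-Hochberg over 9073 genes, with a threshold of 0.05. The plan fixed before the data were examined named count models for a table of raw counts and limma-trend for a table of normalised values, and the latter was followed. The count models were not run; the recovered reads were tested with limma-voom only. Exact permutation of 3 against 3 libraries cannot give a p under 0.1, so no such test was made for single genes. Fixed lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the 28 lists with at least 3 measured members; the mitochondrially encoded and the eggshell and yolk-protein lists had fewer and were not tested.

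The lists, the test and the rule for named genes were fixed before the data were examined. The rule took eve and run, every measured Toll receptor and pair-rule gene, the 10 largest rises and falls among genes past the threshold with a mean of at least 5 CPM (read counts scaled to a common total of gene reads) and no overlap between groups, and up to 4 members past the threshold from each other list, or up to 3 of a list of interest with none. Of the third part it gave noc alone. Other genes are named because they passed adjusted over their list alone, had the lowest p-values or illustrate a list, and were chosen after their values were seen. Adjustment over a list alone does not allow for the number of lists or of alternatives tried, so some such passes can arise by chance. Toll-4, Toll-9, MstProx and Tehao were not analysed here.

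Replicates were compared before averaging: for pairs within a group, a chi-square of read counts over genes was 16.5 to 87.7 per degree of freedom, so no library was a copy of another. The replicate numbers are shared between groups, and the labels do not state a shared day. The check of pairing therefore rests on the data alone: correlations of same-numbered libraries' deviations from their group means, across genes, were 0.24, 0.37 and 0.22, while those of other pairs were −0.38 to 0.11. By a rule set in advance, with every same-number correlation over 0.1, the numbers were taken to pair the libraries, and fits with the number as a block are given where they change a call.

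The fit was tested on simulated counts with the means, library factors and spread of the real libraries for eve+runt dsRNA against water (9073 genes, 5 runs with 200 changed genes of mean at least 20). It recovered 36.4% of genes changed by 1.5-fold, 62.8% by 2-fold, 84.8% by 4-fold and 93.2% by 8-fold, with a mean of 6.8 false calls per run. Simulated genes varied independently, with the same spread in every library, so no library stood apart. The 200 planted changes also ease the adjusted threshold, so these shares may overstate the recovery in the real data. Alternatives were other pseudocounts, scalings, filters and thresholds, limma-voom on the recovered reads, the replicate block and leaving out each library. Library quality weights, the first principal component as a covariate and a pseudocount of 2 were added after the data were seen. The component was computed from the same values that were then tested, so p-values with it as a covariate may be too small. Calculations used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9.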

Results

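Messenger RNA was measured in embryos of the Drosophila wild-type stock Oregon R at the late blastoderm, the stage at which cells have formed and gastrulation is about to start. The embryos had been injected before cell formation with water, as the control, or with a mixture of double-stranded RNAs (dsRNAs) against even-skipped (eve) and runt (run), which act on the matching transcripts through RNA interference. Eve and Runt are transcription factors made in stripes across the trunk, and the series asks which genes they control. There were 3 libraries of water-injected embryos and 3 labelled as eve+runt dsRNA, here called dsRNA libraries, each from about 50 embryos. The 9073 listed genes took 44461953, 26488720 and 33113717 reads in water replicates 1, 2 and 3, and 49364110, 31734622 and 23234425 in dsRNA replicates 1, 2 and 3. Levels are normalised read counts, as mean ± SD over 3 libraries per group. Log2 fold changes ± SE compare dsRNA with water on the log2(normalised count + 1) scale, which understates the change of genes with few reads.

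Water replicate 2 lay apart from the other 5 libraries. On the first principal component, which held 54.7% of the variance, it scored 60.6 and the others scored between −27.7 and 5.61. The second component held 20% of the variance. On it dsRNA replicates 1, 2 and 3 scored −23.5, −21.7 and 22.9, and water replicates 1, 2 and 3 scored −0.51, 9.14 and 13.7. The dsRNA libraries thus also differed among themselves. Of the 37 measured genes of the segment-polarity, homeotic and later-embryo lists, 31 were lower in this library than in both other water libraries. Of the 17 maternally loaded RNAs, 15 were higher in it than in both.

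Transcripts of run were lower in all 3 dsRNA libraries than in all 3 water libraries, and those of eve were not. The pair-rule gene run (CG1849; BDGP6 chromosome X, 20690670 to 20697321, plus strand) stood at 3131, 2220 and 3557 normalised counts in water replicates 1, 2 and 3 and at 1976, 1922 and 1733 in dsRNA replicates 1, 2 and 3. Its means were 2969 ± 683 and 1877 ± 127 (SD, n = 3 each), a 0.643-fold level with a log2 fold change of −0.64 ± 0.18 (SE). The pair-rule gene eve (CG2328; BDGP6 chromosome 2R, 9979319 to 9980795, plus strand) stood at 2827, 1699 and 3075 in water and at 2922, 2727 and 2325 after dsRNA. Its means were 2534 ± 734 and 2658 ± 304 (SD, n = 3 each), a log2 fold change of 0.11 ± 0.23 (SE) with a 95% confidence interval of −0.44 to 0.66. Over all 9073 genes the limma test gave an adjusted p = 0.999 for both. Adjusted over the 2 targets alone, the limma adjusted p was 0.0184 for run and 0.65 for eve. The call on run over the targets alone was lost without water replicate 1 (adjusted p = 0.0676), without dsRNA replicate 3 (0.0805) and with upper-quartile scaling (0.0548). Without water replicate 2 run stood at −0.83 ± 0.10 and eve turned to −0.16 ± 0.11 (log2, SE). A count per gene does not separate the embryo's transcripts from any injected dsRNA that was sequenced. For eve, an annotated antisense RNA (asRNA:CR43948) overlaps its exon, and its reads cannot be separated unless the counting used strand.

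**Figure D1:**
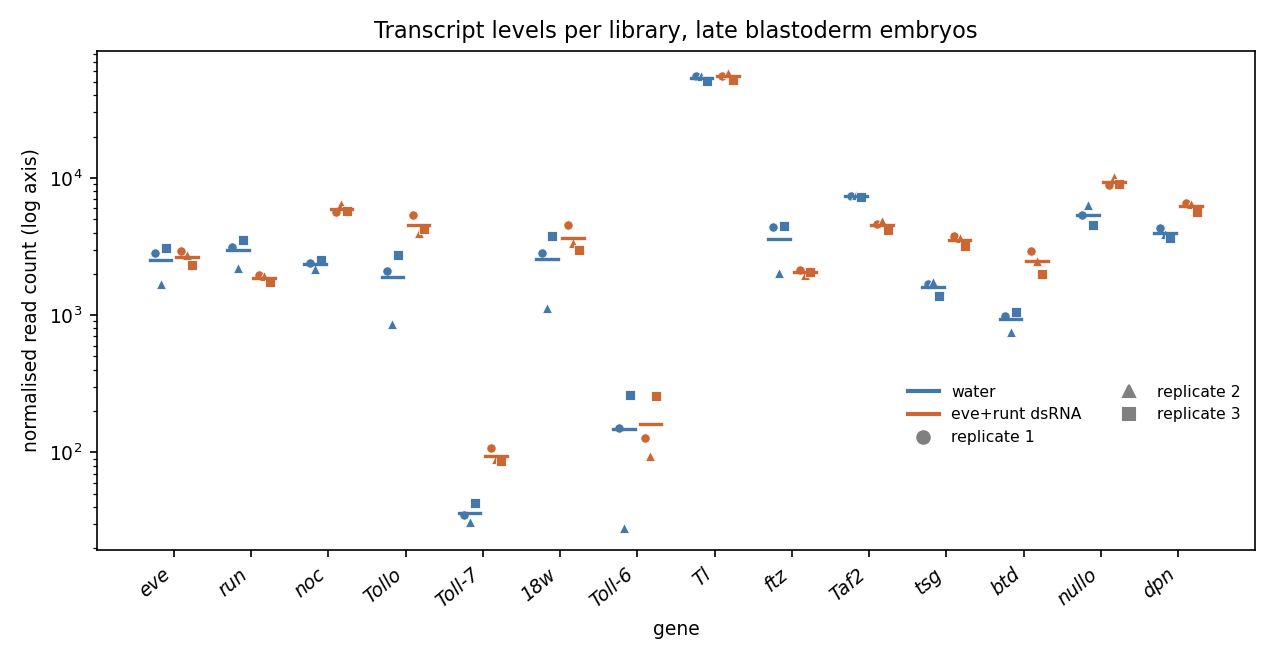
Normalised read counts (log axis) of 14 genes in each of the 6 libraries; points are libraries, with marker shapes for replicates 1, 2 and 3, and bars are group means of 3 water (blue) and 3 eve+runt dsRNA libraries (orange). All dsRNA libraries lay above all water libraries for noc, Tollo, Toll-7, tsg, btd, nullo and dpn and below them for run and Taf2, while eve overlapped between the groups.

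Across the 9073 genes, 1 gene passed the threshold after eve+runt dsRNA in the planned fit, which had no replicate block, and it rose. Directions refer to the libraries so labelled, in which eve itself was not lower. This was noc (CG4491; BDGP6 chromosome 2L, 14490859 to 14494019, plus strand), which encodes a zinc-finger protein named for the loss of ocelli in mutants. Its level was 2350 ± 182 in water and 5955 ± 426 after dsRNA (SD, n = 3 each), 2.53-fold higher with a log2 fold change of 1.34 ± 0.09 (SE; limma adjusted p = 0.0157). It was higher in all 3 dsRNA libraries than in any water library. No gene fell past the threshold with limma-trend, and limma-voom called 3 genes, of which 2 were higher (noc and tsg) and 1 lower (Taf2). At an unadjusted limma p under 0.05 there were 206 genes, a smaller share of the 9073 than the 0.05 that chance gives. On leaving out water replicates 1 to 3 in turn this number was 216, 329 and 271, and on leaving out dsRNA replicates 1 to 3 it was 84, 90 and 560. Regrouping the 6 libraries into other sets of 3 and 3 gave 35 to 1221 such genes. The groups did not overlap for 271 genes that were higher and 305 that were lower after dsRNA, together 6.3% of all genes, where chance gives 10%. The call on noc was lost with the replicate number as a block (adjusted p = 0.244), under which 0 genes passed and 348 had an unadjusted p under 0.05, and on leaving out any library except water replicate 2 (adjusted p between 0.053 and 0.21). Without water replicate 2, 4 genes passed: noc, nullo, tsg and the pair-rule gene ftz, the last of which was lower.

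Behind noc came 5 genes singled out after their values were seen, none of which passed over all genes. Twisted gastrulation (tsg), whose secreted product binds BMP ligands in dorsoventral patterning, stood at 1606 ± 191 in water and 3533 ± 312 after dsRNA (log2 1.14 ± 0.12; limma adjusted p = 0.103). Buttonhead (btd), a head-gap gene, stood at 930 ± 161 and 2479 ± 465 (log2 1.41 ± 0.18; limma adjusted p = 0.363). Deadpan (dpn), a neural precursor gene that also takes part in X-chromosome counting, stood at 3957 ± 357 and 6210 ± 509 (log2 0.65 ± 0.09; limma adjusted p = 0.514). Nullo, needed for the cell membranes of the blastoderm, stood at 5404 ± 876 and 9399 ± 676 (log2 0.81 ± 0.12; limma adjusted p = 0.627). Taf2, a subunit of the general transcription factor TFIID, stood at 7355 ± 116 and 4558 ± 331 (log2 −0.69 ± 0.07; limma adjusted p = 0.103). In each of the 5 genes the 3 dsRNA libraries did not overlap with the 3 water libraries. Exons of dpn and Taf2 overlap annotated genes on the other strand (asRNA:CR44275 and CG34382), so that reads of the pair cannot be separated unless the counting used strand.

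Of the 5 measured Toll-family receptors, leucine-rich-repeat proteins of the cell surface that include receptors needed for the oriented cell rearrangements of germband extension, Toll-7 and Tollo had the highest log2 fold changes. Differences between receptors were not tested. Toll-7 (CG8595; BDGP6 chromosome 2R, 19826578 to 19832973, plus strand) had 36.1 ± 6.02 normalised counts in water and 94.3 ± 11.1 after dsRNA (SD, n = 3 each; log2 1.37 ± 0.23, SE). Tollo (CG6890; BDGP6 chromosome 3L, 15235619 to 15242832, plus strand) had 1895 ± 955 and 4531 ± 750 (log2 1.40 ± 0.41). Levels were 2576 ± 1339 and 3627 ± 802 for 18w (log2 0.64 ± 0.43), 147 ± 117 and 160 ± 86.9 for Toll-6 (log2 0.48 ± 0.83), and 53763 ± 2874 and 54884 ± 3230 for Tl (log2 0.03 ± 0.06), the receptor of maternal dorsoventral patterning. None of the 5 passed limma over all genes (adjusted p = 0.819 for Toll-7 and 0.999 for the others), and 2 of 5 passed adjusted over the list alone, with an adjusted p = 0.00316 for Toll-7 and an adjusted p = 0.0305 for Tollo by limma. With the first principal component as a covariate Tollo passed over all genes (log2 1.15 ± 0.11, limma adjusted p = 0.0308). The component was computed from the values tested, so this SE and p-value may be too small. The list was higher by camera with a preset correlation (median log2 0.64, 5 of 5 genes positive, adjusted p = 0.00029), with an adjusted p = 0.635 with an estimated correlation. The list median was 1.14 without water replicate 3. Tollo was at 860 in water replicate 2 against 2082 and 2743 in the other water libraries, and without that library the list median was 0.13, Tollo stood at 0.91 ± 0.16, Toll-7 at 1.26 ± 0.23, 18w at 0.13 ± 0.19 and Toll-6 turned to −0.44 ± 0.44 (log2, SE). Tollo no longer passed over the list alone without any 1 of the dsRNA libraries, and Toll-7 is left out where a mean CPM of 5 is required.

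No change passed the test among the 7 pair-rule genes other than eve and run, which encode the transcription factors that share the striped patterning of the trunk with them. Fushi tarazu (ftz) stood at 3613 ± 1372 in water and 2053 ± 80.2 after dsRNA (log2 −0.73 ± 0.30). The levels of odd were 2588 ± 1139 and 1822 ± 280 (log2 −0.41 ± 0.34), and those of prd were 1500 ± 612 and 2201 ± 677 (log2 0.61 ± 0.38). The log2 fold changes of hry, opa, slp1 and slp2 were 0.14 ± 0.29, 0.08 ± 0.81, 0.05 ± 0.17 and 0.12 ± 0.39. By limma the adjusted p was 0.999 for each of the 7 over all genes. Of these, 0 of 7 passed adjusted over the list alone (0.32 for ftz), and 1 of 7 (ftz) had an unadjusted p under 0.05. With the replicate number as a block this held for 2 of 7, prd (log2 0.61 ± 0.14) and ftz (−0.73 ± 0.23), and 0 of 7 passed over the list alone. By camera the adjusted p was 0.999 with the preset correlation and 1 with an estimated correlation, and the list's median of 0.08 differed in sign from its mean of −0.02. All 7 genes were lower in water replicate 2 than in both other water libraries. Without it ftz was lower past the threshold over all genes (log2 −1.10 ± 0.08, limma adjusted p = 0.00335), 3 of 7 passed over the list alone (ftz, odd and opa), and hry, opa, slp1 and slp2 turned negative. In that fit prd stood at 0.20 ± 0.24 and odd at −0.81 ± 0.16 (log2, SE). The list was then lower by camera (median −0.34, adjusted p = 5.18e-05), with an adjusted p = 0.683 with an estimated correlation. An annotated antisense RNA (asRNA:CR44592) overlaps an exon of prd.

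**Figure D2:**
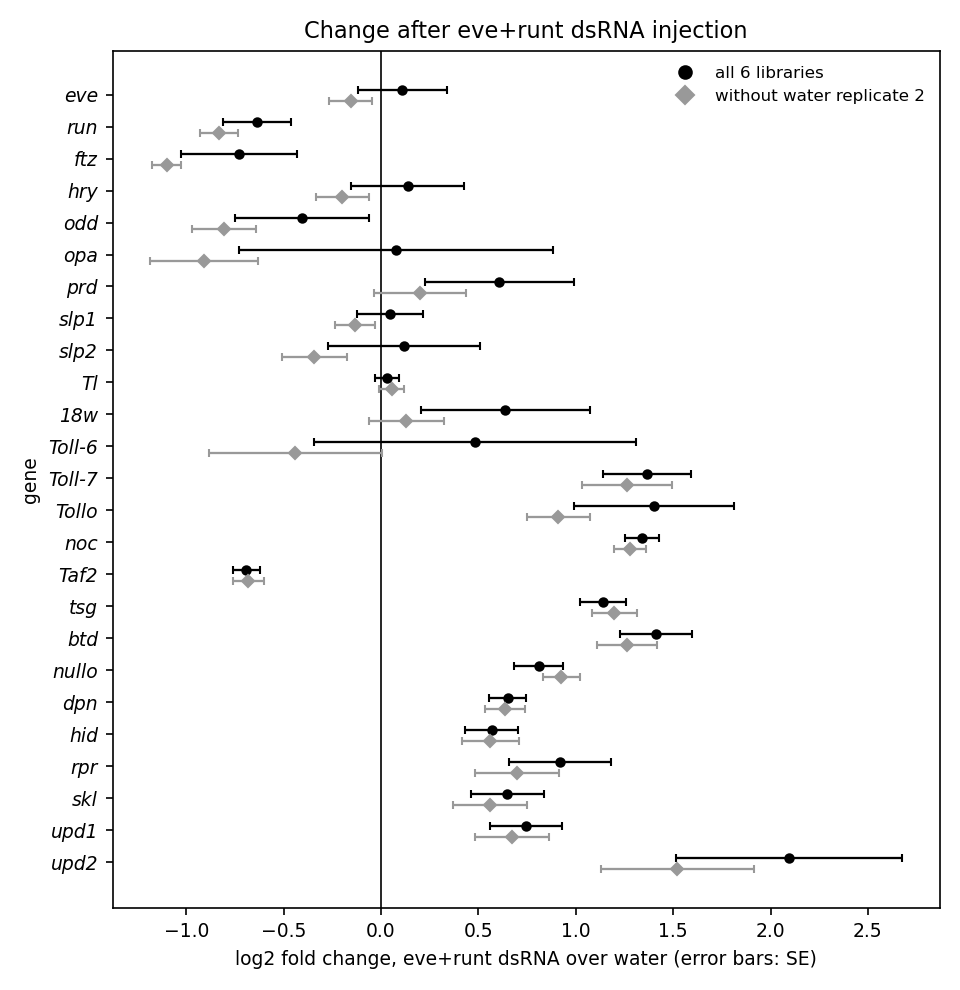
Log2 fold change of 25 genes, eve+runt dsRNA over water, from the limma fit of all 6 libraries (black circles) and of the 5 libraries left without water replicate 2 (grey diamonds); error bars are standard errors. Without that library ftz moved from −0.73 to −1.10 and opa from 0.08 to −0.91, while noc stayed at 1.28 against 1.34.

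The gap, terminal and head-gap genes, which divide the early embryo into broad regions, were higher as a list after dsRNA by camera with the preset correlation (adjusted p = 2.49e-08). The call was lost with the correlation estimated (adjusted p = 0.635 with an estimated correlation) and with fry (adjusted p = 0.803). Of 18 measured members, 17 had a positive log2 fold change (median 0.31), and cnc was the exception at −0.57 ± 0.31. Besides btd, the head genes ems and oc were at 985 ± 345 and 2258 ± 605 in water and at 2075 ± 517 and 4064 ± 772 after dsRNA (log2 1.11 ± 0.31 and 0.87 ± 0.23), with no overlap between groups. The trunk gap genes hb, Kr, kni and gt had log2 fold changes of 0.08 ± 0.09, 0.26 ± 0.19, 0.40 ± 0.19 and 0.27 ± 0.11. With limma 0 of 18 passed over all genes and 1 of 18 adjusted over the list alone (btd, adjusted p = 0.00288). Over the list alone, btd, ems and oc passed with limma-voom and without water replicate 3. With cad they made 4 without water replicate 2 and with library quality weights. There were 5 without dsRNA replicate 3 (with tll and D) and with the first principal component as a covariate (with cad and pdm2). In water replicate 2, 15 of the 18 genes were lower than in both other water libraries, and without it the list median was 0.11 (camera adjusted p = 0.00101). The median was 0.17 without dsRNA replicate 1 and 0.50 without water replicate 3. As a median log2 difference from the mean of the 6 libraries, the list lay at −0.004, −0.721 and 0.001 in water replicates 1, 2 and 3. In dsRNA replicates 1, 2 and 3 it lay at 0.474, 0.139 and −0.05, so dsRNA replicate 3 was not above water replicates 1 and 3.

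Among 7 genes of the JAK/STAT pathway the median log2 fold change was 0.42 (camera adjusted p = 0.00086 with the preset correlation, and an adjusted p = 0.635 with an estimated correlation). The ligand genes upd1 and upd2 stood at 2968 ± 268 and 17.8 ± 9.88 in water and at 5067 ± 1261 and 74.3 ± 31.1 after dsRNA (log2 0.74 ± 0.18 and 2.10 ± 0.58), whereas the receptor dome (0.04 ± 0.05), the kinase hop (−0.01 ± 0.13) and Stat92E (0.05 ± 0.08) lay near 0. In limma 0 of 7 members passed over all genes and 2 of 7 passed adjusted over the list alone (upd1 and upd2, adjusted p = 0.0333 each). The list median was 0.12 without water replicate 2, 0.25 without dsRNA replicate 1 and 0.69 without water replicate 3, and 0.053 (camera adjusted p = 0.0182) where a mean CPM of at least 5 was required. With the replicate number as a block 0 of 7 passed over the list alone, as also without water replicate 1, dsRNA replicate 1 or dsRNA replicate 2.

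Early zygotic genes of cellularisation and cell-death genes made up the remaining lists past the camera threshold with the preset correlation. Of 8 cellularisation genes 7 had positive values (median 0.24), among them slam at 0.23 ± 0.20, bnk at 0.27 ± 0.15 and halo at 0.24 ± 0.23, and nullo was the 1 of 8 that passed adjusted over the list alone (limma adjusted p = 0.00332). Without dsRNA replicate 3, bnk also passed over the list alone. Camera gave this list an adjusted p = 0.00134, and an adjusted p = 0.635 with an estimated correlation. Its median was 0.07 without water replicate 2, 0.07 without dsRNA replicate 1 and 0.42 without dsRNA replicate 3. As a median log2 difference from the mean of the 6 libraries, the cellularisation list lay at 0.022, −0.312 and 0.075 in water replicates 1, 2 and 3. In dsRNA replicates 1, 2 and 3 it lay at 0.374, 0.202 and −0.243, so dsRNA replicate 3 was below water replicates 1 and 3. The cell-death activators hid, rpr and skl stood at 892 ± 51.7, 276 ± 80.2 and 110 ± 14.4 in water and at 1333 ± 202, 515 ± 106 and 172 ± 15.5 after dsRNA (log2 0.57 ± 0.13, 0.92 ± 0.26 and 0.65 ± 0.19). These 3 of 7 members passed adjusted over the list alone (limma adjusted p = 0.0259 each) and 0 of 7 over all genes, and Corp, also listed there, was at −0.30 ± 0.11. Corp passed over the list alone without water replicate 2 and with quality weights or the first principal component as a covariate. The list median was 0.31, with an adjusted p = 0.013 by camera and an adjusted p = 0.696 with an estimated correlation. The cell-death call was lost with the replicate number as a block (camera adjusted p = 0.0578), without water replicate 2 (median 0.03, adjusted p = 0.0967), without dsRNA replicate 1 (0.0665), with a mean CPM of at least 5 (0.0854) and with library quality weights (0.0847). The median was 0.51, 0.61 and 0.50 without water replicate 1, water replicate 3 and dsRNA replicate 3. By the same measure per library the cell-death list lay at 0.096, −0.502 and −0.042 in water replicates 1, 2 and 3. In dsRNA replicates 1, 2 and 3 it lay at 0.43, 0.265 and −0.019. Over the list alone the calls on hid, rpr and skl were lost with the block and without water replicate 1, dsRNA replicate 1 or dsRNA replicate 2.

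Of the 30 lists, 28 had at least 3 measured members and were tested, and 5 of the 28 passed by camera with the preset correlation, while 0 passed with an estimated correlation and 0 with fry. With the first principal component as a covariate, fry passed 2 lists, the pair-rule genes (adjusted p = 0.00454) and the Toll receptors (adjusted p = 0.0118). Since the component was computed from the values tested, these 2 p-values may be too small. In the dorsal ectoderm list (15 genes, median 0.14, camera adjusted p = 0.096), 0 passed over all genes and tsg passed adjusted over the list alone (limma adjusted p = 0.00051), while dpp and zen were at 0.14 ± 0.19 and 0.11 ± 0.13. Among 10 genes of X-chromosome counting and dosage compensation (median 0.02, camera adjusted p = 0.0923), dpn and upd1 passed over the list alone (limma adjusted p = 0.00283 and 0.0267) and 0 over all genes, and the master switch Sxl was at −0.22 ± 0.24. Sxl passed over the list alone without water replicate 2 and with the first principal component as a covariate. The call on upd1 in that list was lost without water replicate 1 or dsRNA replicate 2.

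None of the other lists passed by camera, and with limma-trend on all 6 libraries none of their members passed over all genes or adjusted over the list alone. Under other settings, with no adjustment for the number of lists or settings, some members passed over the list alone. Hsp26 did so with upper-quartile and library-total scaling, limma-voom, a mean CPM of at least 5, without water replicate 2, and with quality weights or the first principal component as a covariate. Quality weights also passed 5 Notch and Bearded genes (Ser, E(spl)m6-BFM, Brd, Tom and Ocho), Egfr, aub, AGO2 and Hsp23. The covariate passed hh, Dfd, abd-A, SoxN and Ocho. Of these genes, hh and AGO2 also passed without water replicate 3, Ocho without water replicate 2, and Ser and Brd without dsRNA replicate 3. Among patterning lists the median log2 fold change was 0.09 for 19 segment-polarity genes (camera adjusted p = 0.621), 0.07 for 8 homeotic genes (0.433), 0.18 for 15 mesoderm genes (0.5), 0.30 for 14 neuroectoderm genes (0.199), −0.22 for 16 Notch ligand, Enhancer of split and Bearded genes (0.199) and 0.02 for 10 EGF-receptor and FGF genes (0.909). Within them hedgehog (hh) had 65.9 ± 38.6 normalised counts in water and 145 ± 21.3 after dsRNA (log2 1.29 ± 0.44), and wingless (wg) and engrailed (en) were at −0.09 ± 0.31 and −0.15 ± 0.34. Among surface and junction proteins the medians were 0.20 for 15 other leucine-rich-repeat proteins (camera adjusted p = 0.083, and 0.0384 with the replicate number as a block, where it was 0.986 with an estimated correlation), 0.05 for 24 adhesion receptors (0.172) and 0.01 for 16 actomyosin and polarity genes (0.479). Medians were −0.13 for 17 maternal RNAs (0.114), −0.13 for 12 pole-cell genes (0.189), 0.19 for 10 later-embryo genes (0.465) and 0.29 for 8 yolk and blood genes (0.758). For lists of RNA-interference, defence and stress genes, medians were 0.01 for 8 RNA-interference genes (0.714), −0.01 for 11 immune genes (0.987), −0.17 for 9 heat-shock genes (0.781) and 0.01 for 9 wound genes (0.987). Medians were 0.01 for 8 cell-cycle genes (0.909), −0.00 for 88 ribosomal protein genes (0.955) and 0.01 for 11 histone genes (0.986). The camera direction or the mean differed in sign from the median for the RNA-interference, immune, heat-shock, wound, cell-cycle and histone lists. In water replicate 2 all 8 homeotic genes and 17 of the 19 segment-polarity genes were lower than in both other water libraries, and 11 of the 12 pole-cell genes were higher. Without that library camera with the preset correlation called the segment-polarity (median −0.28, adjusted p = 0.0268), homeotic (−0.43, 0.0398), mesoderm (−0.33, 0.035), Notch and Bearded (−0.53, 0.0051) and ribosomal protein lists (−0.028, 0.035), all lower. With an estimated correlation the adjusted p was 0.683 for the first 4 of these and 0.91 for the ribosomal list. Without water replicate 3 the same test called the segment-polarity (median 0.13, adjusted p = 0.0338), homeotic (0.59, 0.0164), mesoderm (0.40, 0.0215), neuroectoderm (0.60, 0.0147), dorsal ectoderm (0.27, 0.0147), other leucine-rich-repeat (0.30, 0.0147) and X-chromosome counting lists (0.091, 0.0147) higher. It called the maternal list (−0.17, 0.0147) lower. With an estimated correlation the adjusted p was 0.561 to 0.64 for these 8 lists. Without water replicate 1 it called the adhesion receptor (median 0.13, adjusted p = 0.0204), other leucine-rich-repeat (0.27, 0.0374), dorsal ectoderm (0.17, 0.0372) and ribosomal protein lists (0.022, 0.0065) higher. The maternal (−0.24, 0.0065) and pole-cell lists (−0.23, 0.00416) were called lower. With an estimated correlation the adjusted p was 0.598 to 0.79 for these 6. Without dsRNA replicate 3 the Notch and Bearded list was called lower (−0.46, 0.0163), with an adjusted p = 0.975 with an estimated correlation. Without water replicate 2 the medians were −0.031 for the dorsal ectoderm list (camera adjusted p = 0.981), −0.10 for neuroectoderm (0.981) and −0.39 for later-embryo genes (0.202). They were −0.28 for yolk and blood genes (0.202), 0.017 for maternal RNAs (0.343) and 0.012 for pole-cell genes (0.53). For other leucine-rich-repeat proteins the median was −0.077 (0.981) and for adhesion receptors −0.031 (0.507). For EGF-receptor and FGF genes it was −0.23 (0.242), and for heat-shock genes −0.24 (0.818). Without water replicate 3 the medians were 0.29 for EGF-receptor and FGF genes (camera adjusted p = 0.171), 0.15 for heat-shock genes (0.0915) and 0.52 for later-embryo genes (0.121).

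**Figure D3:**
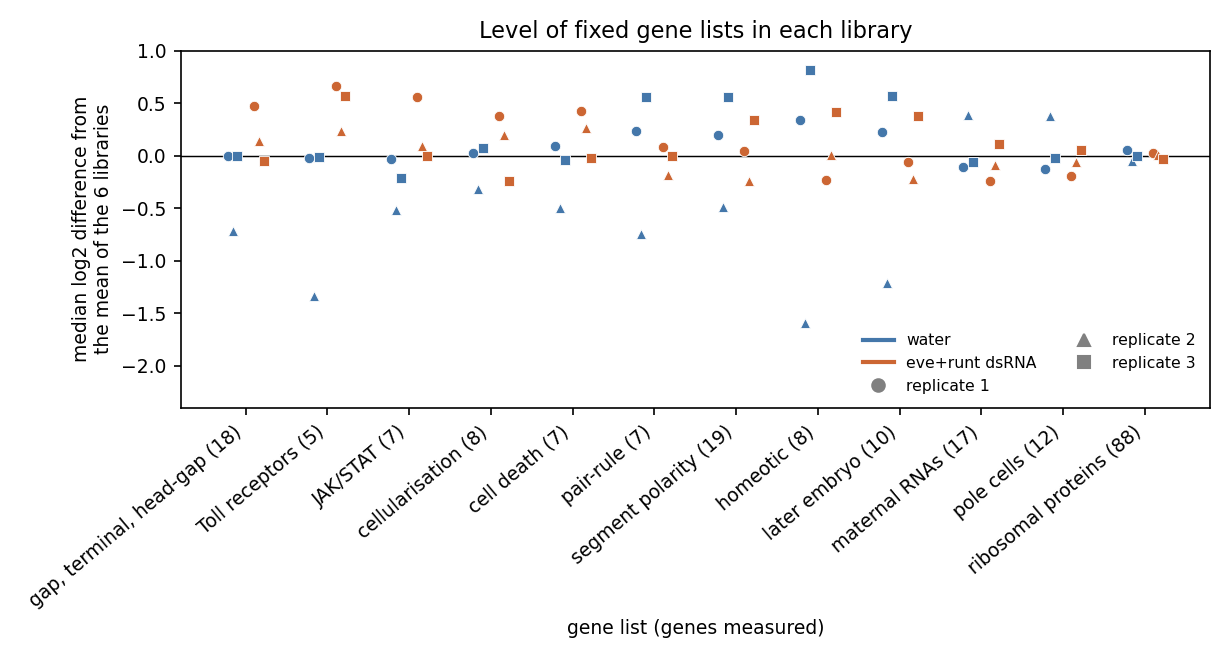
Median log2 difference of each gene list from the mean of the 6 libraries, for 12 of the fixed lists, with 3 water (blue) and 3 eve+runt dsRNA libraries (orange) and marker shapes for replicates 1, 2 and 3. Water replicate 2 lay at −1.59 for the homeotic list and −1.34 for the Toll receptors and at 0.39 for the maternal RNAs. The dsRNA replicate 3 lay below water replicates 1 and 3 for the gap and cellularisation lists and above both for the Toll receptor and JAK/STAT lists.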

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

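Alternatives with library quality weights, with the first principal component as a covariate and with a pseudocount of 2 were chosen only after the data were seen. Calls with the component as a covariate may be too many, since it was computed from the values tested. The planned count-model fits were not run (their scalings were tried within limma), and omitting the filter is void because the filter removes 0 genes. With the alternatives run, the number of changed genes was 1 by default, 2 with library-total scaling, 3 with limma-voom, 0 with the replicate block, 0 at an adjusted p under 0.01, 0 to 4 with 1 library left out, 5 with library quality weights and 6 with the first principal component as a covariate. The gene noc was among them wherever at least 1 gene was called. Lists past the threshold numbered 5 by default, 9 with a mean of at least 5 CPM (adding dorsal ectoderm, neuroectoderm, other leucine-rich-repeat, adhesion and X-chromosome counting lists and losing cell death), 4 to 13 with 1 library left out, and 0 both with an estimated correlation and with fry; fry called 2 lists (pair-rule genes and Toll receptors) with the principal component as a covariate. In camera that covariate added the pair-rule and Notch lists, and quality weights those and the ribosomal list, all lower. The log2 fold change of eve reversed with library quality weights (−0.045) and with the principal component (−0.015), and ranged from −0.16 to 0.27 with 1 library left out. By contrast run stayed negative in every alternative. With the same 2 settings the values were −0.40 and −0.010 for Toll-6, −0.081 and −0.034 for hry, −0.82 and −0.43 for opa, −0.18 and −0.047 for slp1 and −0.17 and −0.10 for slp2, and opa was also negative with limma-voom (−0.082). With 1 library left out the ranges were −0.016 to 0.077 for Tl, −0.44 to 1.14 for Toll-6, −0.20 to 0.38 for hry, −0.91 to 0.72 for opa, −0.13 to 0.14 for slp1 and −0.34 to 0.43 for slp2. Fewer libraries were fitted in these; the cause of the other reversals was not tested. Over the 30 genes and lists followed through the alternatives, eve and run included, 487 values kept direction and side of the threshold, 11 lost a call (noc and the cell-death list), 15 gained one and 23 reversed. The 487 do not measure stability. They include the void setting without a filter and median-of-ratios scaling, which equals the authors' scaling, and many are genes without a call in either fit. The replicate block ended the calls on noc and on the cell-death list and the list-alone calls on hid, rpr, skl and, in the JAK/STAT list, upd1 and upd2. It added a call on the list of other leucine-rich-repeat proteins (camera adjusted p = 0.0384, and 0.986 with an estimated correlation) and changed no other call. Scalings moved the median of all genes by at most 0.04 (log2).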

Other observations

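The tests below were chosen only after the result was seen, except that of embryo age for the proteasome subunits, which was set down before its value was known. For the 18 measured subunits of the 19S regulatory particle of the proteasome, the cap that feeds ubiquitin-tagged proteins to the proteolytic core, the log2 fold change was negative (median −0.33, SD 0.14 across genes), with 11 genes at an unadjusted limma p under 0.05 and 0 past the adjusted threshold. The 11 became 7, 10 and 8 on leaving out water replicates 1 to 3 in turn, and 6, 5 and 13 on leaving out dsRNA replicates 1 to 3. The 14 genes of the 20S core had a median of −0.04, and the 8 genes of the CCT chaperonin, which folds actin and tubulin, a median of −0.19. The set was not among the fixed lists, was picked because its genes were seen to have negative values, and has no set test of its own.

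The 20S median lay 0.289 above the 19S median. This does not decide on a shift of equal size across the whole proteasome. The 19S set was picked for its negative values, which by itself favours a gap to a set not picked that way. A shift of the core, smaller or not, stays open, since 13 of 14 core genes were also negative (8 to 14 over the alternatives). So were 8 of 8 CCT genes (7 or 8). Under the scaling that raised it most the 19S median was −0.29, and 17 of 18 genes stayed negative. A scaling moves all genes by nearly the same amount. This argues only against the choice among the scalings tried as the cause. With the first principal component as a covariate the median was −0.30, which argues against an age difference along that component as the whole cause. That component mainly sets water replicate 2 apart, so other differences in embryo age between the groups stay open. Of the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, 1 gave an absolute median this large, the real one, and the highest other was 0.248; because the set was picked on the real grouping, this order says nothing about chance. An effect of the injected dsRNAs may remain as a hypothesis, since other differences between the groups of embryos were not tested.

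Water replicate 2 may hold younger embryos. The genes of the segment-polarity, homeotic and later-embryo lists were lower in it by a median log2 difference of −1.31 from the mean of the other water libraries, and the maternal list was higher by 0.56. Low depth is argued against, since the library with the fewest reads, dsRNA replicate 3, scored −14.6 on the first principal component against 60.6 for water replicate 2. Differences in injection or handling of that collection stay open, and no biological group of the design bears on it.

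The higher levels of noc, tsg, btd, nullo and dpn and the lower level of Taf2 had a median absolute log2 fold change of 0.97. With the first principal component as a covariate the median was 1.03. This does not decide on embryo age, since that component mainly sets water replicate 2 apart. These genes were also picked partly for low p-values, and such genes vary little within groups. The lowest median was 0.98 over library-total and upper-quartile scaling. A scaling moves all genes by nearly the same amount, and these genes moved in both directions. The values therefore show only that the choice among the scalings tried does not account for them. What stays open is embryo age, a direct or indirect effect of losing Runt or Eve, and an off-target effect of the dsRNAs. Transcripts of eve were not lower, so a loss of Eve is not shown. Any other difference between the collections stays open too, and these causes could not be separated here. For the number of changed genes, the 10 splits are too few for a share under 0.05: the real split called 1 gene and the highest other split 0, and 1 of the 10 splits called as many. For the number of lists past the threshold, the real split called 5 and the highest other split 13, and 9 of the 10 splits called at least as many. If the replicate numbers pair the libraries, which rests on the data alone, the real split compares with the 3 others that part every pair. Those exchange the libraries of 1 replicate number, and they called 0 genes each, and 3, 7 and 10 lists. With the replicate number as a block, limma called 0 genes for the real split.

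A change in the dose of X-linked transcripts as a whole was looked for because run is one of the X-linked elements that the embryo counts to set its sex. The median log2 fold change of 1535 X-linked genes lay −0.0037 from that of 7429 autosomal genes, so no shift of the X-linked median was seen. This cannot exclude such a change, since run transcripts fell only to a 0.643-fold level and the spread of the genes was not assessed. A median over all X-linked genes also cannot show a change confined to some of them. Among the 25 genes named in full, tsg, btd, nullo, upd1 and upd2 were X-linked and higher without overlap between groups. The autosomal noc, dpn, Tollo, Toll-7, hid, rpr and skl were higher in the same way. These X-linked genes were chosen after their values were seen, and an excess of X-linked genes was not tested.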
